A study of Homo sapiens with 3 samples.

How the data were processed

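RNA was measured in 3 libraries of Hep3B cells, a human hepatocellular carcinoma line, collected at day 2 of siRNA treatment. Per the labels, 1 library came from cells given a control siRNA (si-Control) and 2 from cells given siRNA against CPSF6 (si-CPSF6 #1 and #2), all at 40 uM as the labels state it. The labels do not say whether #1 and #2 are different siRNAs, separate cultures or repeat libraries. Sequencing was single-end, 75 nt, per the series description. The labels name a SMARTER mRNA-Seq kit, whereas the title of the deposited table names QuantSeq 3′ mRNA-Seq; the 2 kits place reads differently along a transcript, and the sources do not settle which was used. Reads were aligned with Bowtie2, per the submitters' processing notes. The counting tool, its handling of strand and multiply mapped reads, and the genome build are not given in the sources used here. Coordinates below are those of the deposited table, whose contig names follow the older human build style.

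The deposited table held raw read counts per gene row, per the file headers, with 25736 rows used here, of which 7652 had no count in any library. A further line was emptied for this work and is not analysed here. Per the file headers, the authors also deposited log2 normalized values, which equalled log2 of a scaled count plus 1 with a single scale per library. The deposited fold changes of each si-CPSF6 library over si-Control, per the file headers, equalled 2 to the power of the difference between those log2 values. The counts were used for every test, and the deposited log2 and fold values were used to check the columns and to give the authors' own CPSF6 ratio. No row lay on the mitochondrial chromosome, and 1561 rows shared 286 gene symbols with another row. Such rows were kept in the test and were not named.

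Counts were analysed in R 4.3.3 with edgeR 4.0.16. Rows were kept by filterByExpr with the group and its minimum count of 10, which left 12923 rows, and libraries were scaled by TMM. The test was edgeR's quasi-likelihood F test with robust empirical Bayes, both si-CPSF6 libraries against si-Control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit had 1 residual degree of freedom, and the lone control was assumed to vary like the si-CPSF6 libraries. The common dispersion was 0.0419. Standard errors of log2 fold changes were derived from the F statistic. CPM are counts per 1e6 counts with TMM scaling, given for si-CPSF6 as the mean ± SD of 2 libraries. Ratios of single libraries to the control are on a log2 CPM scale with a prior count of 2.

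Named genes followed a rule fixed before the data were examined. It took CPSF6 and the 12 called genes in each direction with the largest fitted fold, at least 1.5-fold the same way in each library, with a mean of at least 10 CPM and a symbol of their own. It also took up to 4 members with the smallest p from each gene list. Not every gene the rule took is named. Genes named outside that rule are said to be so. The 29 gene lists were likewise fixed beforehand. Lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with an estimated one, and with fry. Each list's median was also placed among 10000 random lists matched on mean expression. The simulated list described next held independent genes, so it bears on power only and not on lists whose genes vary together. With 1 residual degree of freedom the estimated-correlation test has little power: on simulated counts, a list of 20 genes all moved 1.5-fold gave p = 4.15e-20 with the preset value and p = 0.0632 with the estimated one.

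The agreement of the si-CPSF6 libraries was set beside 100 simulated data sets in which no gene differed and both libraries were compared with the same control. On simulated counts for si-CPSF6 against si-Control (12454 genes), the test called 0% of genes changed 1.5-fold, 40.4% of those changed 2-fold, 54.0% of those changed 3-fold and 65.3% of those changed 4-fold. Among genes with a mean of at least 50 CPM those shares were 0%, 80.0%, 93.3% and 100%. A simulation with changes gave 1 false call, and another with no changes gave 0 calls.

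Alternatives were RLE size factors or library size alone in place of TMM, other filters, other prior counts, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, no robust step, a test against a fold of 1.5, and leaving out each si-CPSF6 library. GC content, transcript length and 3′ UTR length came from GENCODE 29 transcripts matched by RefSeq accession, without use of their coordinates, for 94.4% of tested rows; the trend on GC content and length was a loess with span 0.5, and its interval used 10000 bootstrap draws. Camera p-values of 2 further lists, made after the data were seen, were adjusted over those 2 lists alone. Figures and transcript lengths were made with Python 3.11.15 and matplotlib 3.10.9.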

Results

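Gene expression was compared between cells labelled as given siRNA against CPSF6 and cells given control siRNA, in Hep3B, a human hepatocellular carcinoma line that makes many liver plasma proteins. CPSF6 encodes a subunit of cleavage factor Im, a complex that binds pre-mRNA near poly(A) sites. The si-Control library held 5264772 counts, the library labelled si-CPSF6 #1 held 2386262 and the library labelled si-CPSF6 #2 held 2577637. Counts were found in 16748, 15642 and 15721 gene rows, respectively. A count of 10 had an exact Poisson 95% interval of 4.8 to 18.4, and 3 counts corresponded to 0.570, 1.26 and 1.16 CPM in the same order; such intervals cover counting error only. The control was not replicated, and no source says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

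CPSF6 mRNA (chromosome 12, 69633317 to 69668138, plus strand) was not detectably lower over both libraries labelled si-CPSF6, while in #2 alone it was lower by more than counting error. It stood at 64.5 CPM in si-Control (328 counts), 69.8 CPM in the library labelled si-CPSF6 #1 (167 counts) and 49.4 CPM in the library labelled si-CPSF6 #2 (130 counts). The ratio to si-Control was 1.08 for #1 (exact binomial 95% interval 0.892 to 1.31) and 0.765 for #2 (0.620 to 0.940). Over both libraries the fitted log2 fold change was -0.12 (SE 0.29, edgeR quasi-likelihood adjusted p = 0.958), with a 95% interval on the fold of 0.625 to 1.36. In the authors' deposited table the CPSF6 ratios were 1.06 and 0.754. The transcript level of the target was thus not detectably changed in #1. In #2 it was modestly lower, judged against counting error only, which leaves out other variation between libraries. Every direction below is that of libraries named by their labels, not of a measured loss of CPSF6.

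**Figure D1:**
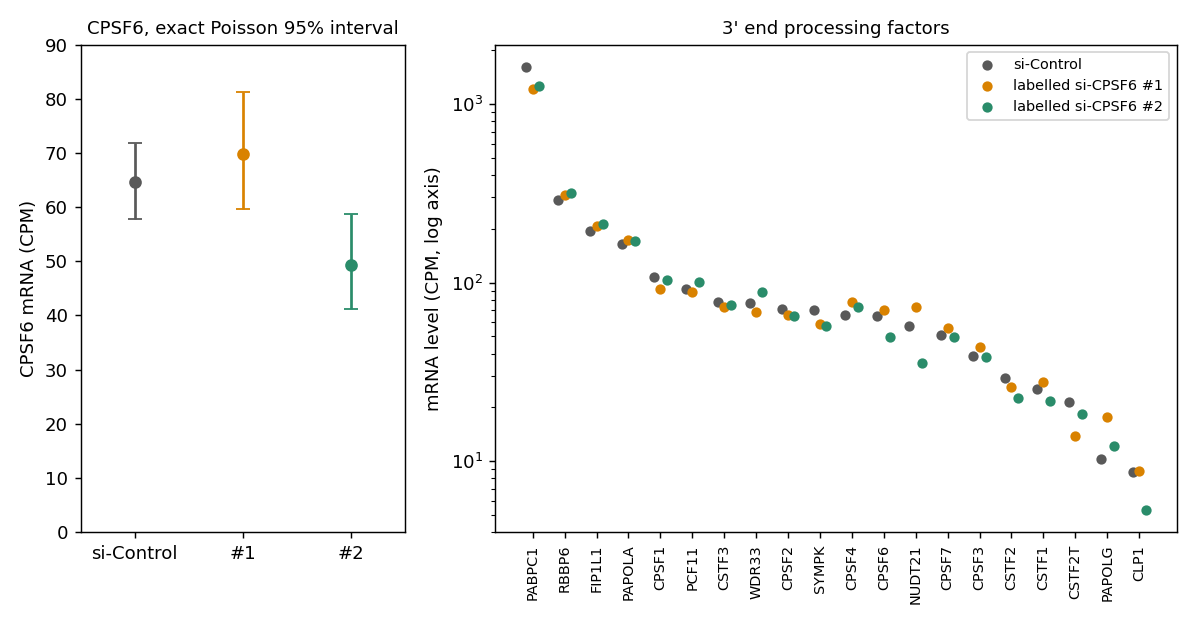
Left, CPSF6 mRNA in CPM for each library, with points for the value and bars for the exact Poisson 95% interval: 64.5 in si-Control, 69.8 in #1 and 49.4 in #2. Right, CPM on a log axis of the 20 tested 3′ end processing factors, CPSF6 included, in the same libraries, 1 point per library; none of the 20 passed the test.

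The list of 3′ end processing factors, which holds CPSF6 itself, was not called either. Among 20 tested factors, CPSF6 included, 0 passed edgeR's test (1 had an unadjusted p under 0.05, 1 was called lower when adjusted over the list alone, and DESeq2 and limma-voom called 1 each), and the list had a median log2 fold change of -0.05 (camera adjusted p = 0.749). The median was 0.04 in #1, -0.06 in #2 and 0.01 with library size alone. PABPC1, a cytoplasmic poly(A)-binding protein, came nearest, at 1618 CPM in si-Control and 1221 and 1256 CPM in the other libraries (log2 fold change -0.39, SE 0.12, adjusted p = 0.0528). SYMPK, PAPOLG and CSTF2T had log2 fold changes of -0.28, 0.53 and -0.42, all with adjusted p of 0.878 or above. Of 18 tested genes reported to change 3′ UTR length with cleavage factor Im, 0 passed (1 at an unadjusted p under 0.05, 1 lower when adjusted over the list alone, 0 by DESeq2 and 1 by limma-voom). The median of this list, 0.03, differed in sign from its mean, -0.04, and from the direction of the test (camera adjusted p = 0.968), and was -0.04 in #1 and 0.06 in #2. The cell cycle gene CCND1 had 52.5 CPM in si-Control and 24.3 ± 7.55 CPM (SD, n = 2) in the libraries labelled si-CPSF6 (log2 fold change -1.11, adjusted p = 0.0923); VMA21, NQO1 and SIN3A stood at -0.56, 0.77 and 0.33, with 1.15 in #1 and 0.22 in #2 for NQO1. Of 22 SR proteins and splicing regulators, 0 passed over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom; camera adjusted p = 0.509). SRSF1, SRSF7, U2AF1 and TRA2A had values of -0.48, -0.42, 0.25 and 0.30. Gene-level counts do not show which poly(A) site was used.

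Between si-Control and the libraries labelled si-CPSF6, 225 of 12923 gene rows differed (edgeR quasi-likelihood, adjusted p under 0.05): 56 were higher and 169 lower in the libraries labelled si-CPSF6. Of these, 19 were higher and 62 lower by at least 2-fold, and 1258 rows had an unadjusted p under 0.05. The clearest rise was in AREG, an EGF receptor ligand, from 157 CPM to 639 and 497 CPM (log2 fold change 1.85, SE 0.16, adjusted p = 1.29e-28). The AREG row spans chromosome 4 from 75310815 to 75490485, and how reads of a near-identical gene copy were counted is not known. The liver-secreted growth factor binder IGFBP1 rose from 12 to 46.1 ± 1.95 CPM (SD, n = 2; 1.94, SE 0.42), the tryptophan-degrading enzyme KYNU from 11.4 to 44.8 ± 7.53 CPM (1.97, SE 0.43) and the aldo-keto reductase AKR1C1, which has close paralogs, from 11 to 44.2 ± 10.9 CPM (2.00, SE 0.43). HKDC1, a hexokinase family member, rose from 37.0 to 98.2 ± 2.41 CPM. JPH1 had the largest fitted rise among the called genes taken by the naming rule (2.63, SE 0.74, adjusted p = 0.0272), from 14 counts in si-Control. Rises were also found in the lncRNA LOC100133077, ZFYVE1, the calcium-binding proteins S100P and S100A11 and the xenobiotic-metabolising CYP1A1, with log2 fold changes from 1.27 to 1.69 (S100A11 0.84 in #1 and 1.58 in #2).

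The largest fall among the named genes was in KNG1, the plasma protein kininogen, with 148 counts in si-Control, 14 in #1 and 2 in #2 (log2 fold change -3.16, 95% interval -4.37 to -1.94, adjusted p = 9.66e-05). The small GTPase RAP1B fell from 44.3 to 10.3 ± 2.12 CPM (-2.10, SE 0.46). CXCL1, a chemokine, fell from 322 to 111 ± 14.4 CPM (-1.53, SE 0.18, adjusted p = 1.18e-14), and HSD17B12, an enzyme of fatty acid elongation, from 196 to 64.5 ± 30.3 CPM (-1.60, SE 0.22). TBPL1, TEN1, ZNF853, the metalloproteinase inhibitor TIMP3, the cholesterol ester hydrolase NCEH1, ELOVL6, FABP1 and WDR45B fell with log2 fold changes from -2.04 to -1.54 (TIMP3 -1.19 in #1 and -2.73 in #2). Of the 225 called rows, which were chosen on both libraries, 194 were at least 1.5-fold from the control the same way in #1 and 164 in #2. Scaled by library size alone, 83 rows were higher and 121 lower (59.3% lower, against 75.1% with TMM), and TBPL1 and TEN1 were no longer called. DESeq2 gave an adjusted p for 4030 rows, and not for every named gene. It called 78 rows and not HSD17B12, while limma-voom called 477 and not JPH1.

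**Figure D2:**
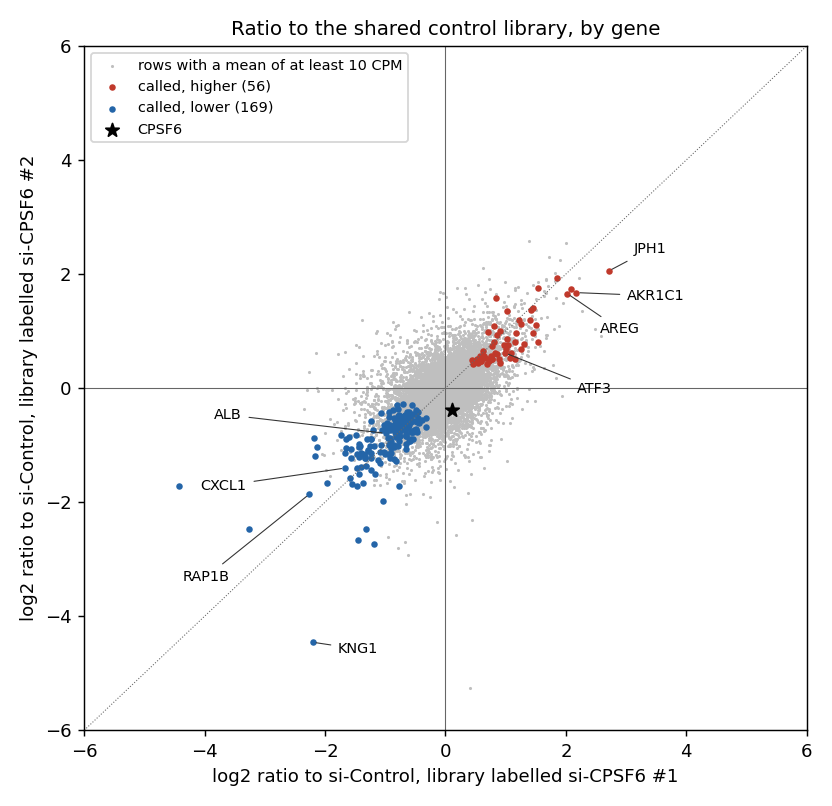
Log2 ratio to the shared si-Control library for each gene row, #1 on the horizontal and #2 on the vertical axis, with rows of at least 10 CPM in grey, called rows in red (56 higher) and blue (169 lower), and CPSF6 as a star. Called rows, chosen on both libraries, lie in the lower left and upper right, while CPSF6 lies at 0.11 and -0.38; the shared control by itself tilts the cloud along the diagonal.

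Hepatocyte secreted and identity genes were lower as a list. Of 24 tested hepatocyte secreted and identity genes, 8 fell and 0 rose (12 fell when adjusted over the list alone), and the list was called lower (camera adjusted p = 5.02e-15; adjusted p = 0.634 with an estimated correlation). Its median log2 fold change was -0.56 (-0.57 in #1, -0.50 in #2). Albumin mRNA (ALB) fell from 4047 to 2183 ± 215 CPM (SD, n = 2; -0.89, SE 0.11, adjusted p = 2.42e-13), transferrin (TF) from 750.0 to 351 ± 30.3 CPM (-1.09, SE 0.13), apolipoprotein B (APOB) from 2876 to 1614 ± 205 CPM (-0.83, SE 0.11) and APOH from 187 to 80.4 ± 34.5 CPM (-1.21, SE 0.21). The other 4, named after their values were seen, were APOA2, APOE, the retinol carrier RBP4 and the transcription factor CEBPA, with log2 fold changes of -0.48, -0.53, -0.62 and -0.68 (APOE -0.80 in #1 and -0.30 in #2). Of 14 complement and coagulation genes, 1 fell and 0 rose (2 fell when adjusted over the list alone), and the list was called lower (camera adjusted p = 0.000242; adjusted p = 0.634 with an estimated correlation). Its median was -0.47, with -0.64 in #1 and -0.26 in #2. Complement factor I (CFI) fell from 75.6 to 32.6 ± 6.52 CPM (-1.21, SE 0.31, adjusted p = 0.0117). C3, F7 and F5 had values of -0.40, -0.64 and -0.54, with -0.60, -0.29 and -0.84 in #1 and -0.23, -1.09 and -0.29 in #2, and 11 of the 14 genes lay below 0. Of 18 ER chaperone and unfolded protein genes, 1 fell and 0 rose (3 fell when adjusted over the list alone), and the list was called lower (median -0.19, camera adjusted p = 0.000819; adjusted p = 0.634 with an estimated correlation). The disulfide isomerase PDIA3 fell (-0.86, SE 0.15, adjusted p = 6.24e-06), while CALR, SDF2L1 and XBP1 stood at -0.37, -0.48 and -0.40. The median of the ER chaperone list lay at percentile 5.12 of matched random lists. DESeq2 gave an adjusted p for 14 of the 24 hepatocyte genes and called 4, APOH not among them. Among the complement and coagulation genes it gave an adjusted p for 4 and called 0, so CFI was not called. Of the ER chaperone genes it called 1.

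Cholesterol synthesis genes were lower as a list. Of 20 cholesterol synthesis genes, 3 fell and 0 rose (5 fell when adjusted over the list alone), and the list was called lower (median -0.39, camera adjusted p = 4.15e-08; adjusted p = 0.634 with an estimated correlation). In it, 19 genes lay below 0. HMGCS1, which makes the precursor of mevalonate, fell from 683 to 408 ± 36.6 CPM (-0.74, SE 0.13, adjusted p = 1.34e-05), FDPS fell by 0.41 on the log2 scale, and DHCR7 had a value of -0.63 (adjusted p = 0.0941). Of 20 fatty acid and triglyceride genes, 5 fell and 1 rose (6 and 2 when adjusted over the list alone), and the list was called lower (camera adjusted p = 0.00266; adjusted p = 0.634 with an estimated correlation). Its median was -0.37, with -0.53 in #1 and -0.18 in #2. The liver fatty acid binding protein FABP1 fell from 94.7 to 31.2 ± 3.79 CPM (-1.60, SE 0.30), the elongase ELOVL6 from 52.3 to 17.1 ± 0.0295 CPM (-1.61, SE 0.39), the desaturase SCD from 1109 to 716 ± 103 CPM (-0.63, SE 0.12) and the fatty acid synthase FASN from 791 to 511 ± 24.3 CPM (-0.63, SE 0.13). ACLY, named after its value was seen, fell by 0.54. PLIN2, a coat protein of lipid droplets, went the other way, from 406 to 675 ± 83.3 CPM (0.73, SE 0.14, adjusted p = 3.81e-05). FDPS was not called by DESeq2 or with library size alone. DESeq2 gave an adjusted p for 10 of the 20 fatty acid and triglyceride genes and called 4.

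Integrated stress response genes were higher as a list. Of 18 integrated stress response genes, 4 rose and 0 fell (7 rose and 1 fell when adjusted over the list alone), and the list was called higher (median 0.41, camera adjusted p = 2.22e-07; adjusted p = 0.634 with an estimated correlation). In it, 17 genes lay above 0. PPP1R15A, the phosphatase subunit that reverses eIF2-alpha phosphorylation, rose from 89.9 to 188 ± 49.0 CPM (1.06, SE 0.20, adjusted p = 5.07e-05), and the transcription factor ATF3 from 195 to 344 ± 62.9 CPM (0.82, SE 0.16). STC2 rose by 0.65 and the mitochondrial folate enzyme MTHFD2 by 0.66 on the log2 scale. Of 20 NRF2 target genes, 2 rose and 0 fell (5 and 2 when adjusted over the list alone), and the list was called higher (camera adjusted p = 0.00266; adjusted p = 0.634 with an estimated correlation). Its median was 0.37, with 0.49 in #1 and 0.23 in #2. The 2 that rose were AKR1C1, given above, and sulfiredoxin SRXN1, from 185 to 281 ± 9.96 CPM (0.60, SE 0.17, adjusted p = 0.0209). AKR1C2, a close paralog of AKR1C1, and the cystine transporter SLC7A11 had values of 1.24 and 0.60 (adjusted p = 0.0911 and 0.127). STC2, MTHFD2 and SRXN1 were not called by DESeq2, and neither was AKR1C1. DESeq2 gave an adjusted p for 15 of the 18 integrated stress response genes and called 2. For the NRF2 target genes it gave an adjusted p for 11 of 20 and called 0.

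Chemokine, ribosomal and respiratory chain genes made up the rest of the called lists. Of 15 NF-kB and cytokine genes, 3 fell and 0 rose (also when adjusted over the list alone), and the list was called lower (median -0.24, camera adjusted p = 2.64e-06; adjusted p = 0.634 with an estimated correlation). Those that fell were CXCL1, given above, the adhesion receptor ICAM1, from 236 to 86.5 ± 2.89 CPM (-1.45, SE 0.20), and the chemokine CCL20, from 1352 to 736 ± 235 CPM (-0.88, SE 0.12; -1.24 in #1 and -0.58 in #2). CXCL8 stood at -0.47 (adjusted p = 0.353). The median of this list was -0.42 in #1 and -0.10 in #2, and DESeq2 did not call CCL20. Of 28 cytosolic ribosomal protein genes, 2 fell and 0 rose (9 fell when adjusted over the list alone), and the list was called lower (median -0.24, camera adjusted p = 2.63e-08; adjusted p = 0.634 with an estimated correlation). In it, 27 genes lay below 0, and RPS2 fell from 847 to 566 ± 5.81 CPM (-0.58, SE 0.13) and RPL30 from 1302 to 895 ± 34.2 CPM (-0.54, SE 0.12). RPS3 and RPL3 had values of -0.34 and -0.41; these genes have many pseudogene copies, and how the authors' counting split shared reads is not known. Of 25 nuclear oxidative phosphorylation genes, 1 fell and 0 rose (8 fell when adjusted over the list alone), and the list was called lower (median -0.13, camera adjusted p = 0.00252; adjusted p = 0.634 with an estimated correlation). NDUFB9, a complex I subunit, fell (-0.47, SE 0.13, adjusted p = 0.0334), and COX7C, NDUFA4 and COX5A stood at -0.47, -0.42 and -0.52. The oxidative phosphorylation median lay at percentile 8.32 of matched random lists, and NDUFB9 was not called by DESeq2 or with library size alone.

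**Figure D3:**
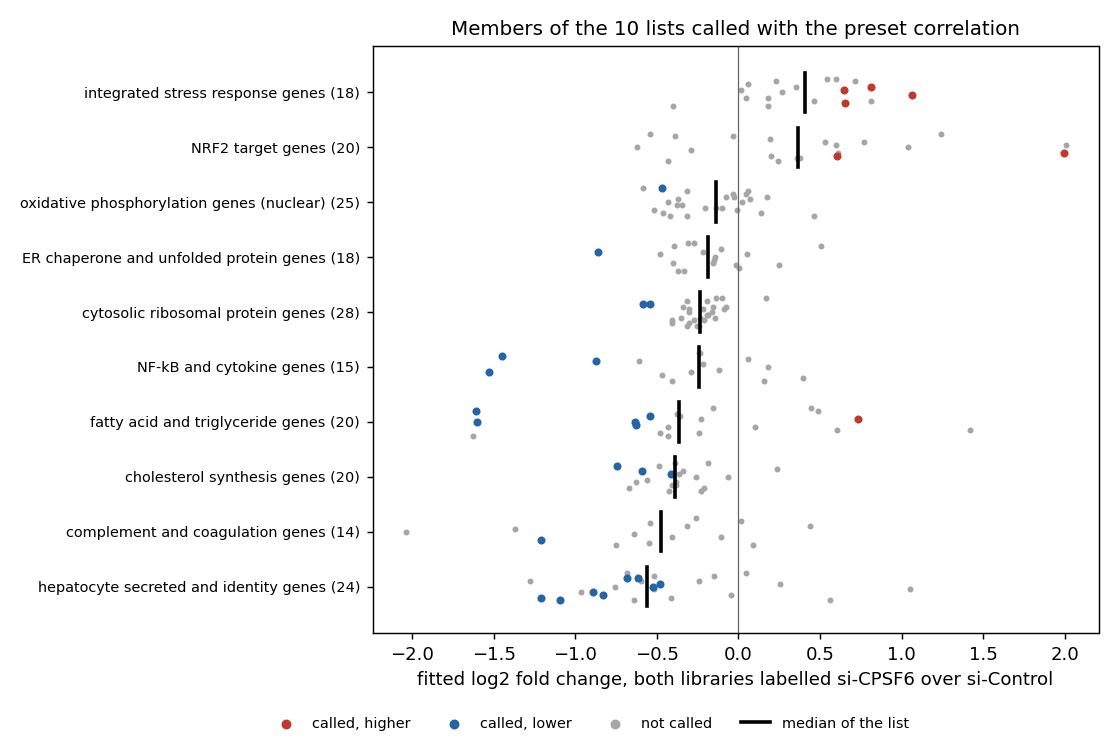
Fitted log2 fold change (both libraries labelled si-CPSF6 over si-Control) of the members of the 10 lists called with the preset correlation, 1 point per gene, red or blue if called and grey if not, with the list median as a black bar and the number of tested genes in parentheses. Medians run from -0.56 for hepatocyte secreted and identity genes to 0.41 for integrated stress response genes; with an estimated correlation the adjusted p was 0.634 for each of these lists.

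Of 27 lists tested, 10 were called by camera with the preset correlation, 2 higher and 8 lower. With an estimated correlation camera called 0 (smallest adjusted p = 0.634). Fry also called 0, and its smallest adjusted p, 0.0563, was that of the YAP and SRF target genes. For the 10 lists called by camera, the fry adjusted p ranged from 0.283 for oxidative phosphorylation to 0.447 for integrated stress response and NRF2 target genes. The other lists were not called by camera with either correlation, although single members of some were. Of 23 DNA replication and S phase genes, the ribonucleotide reductase subunit RRM2 fell from 120 to 45.5 ± 7.62 CPM (-1.39, SE 0.26, adjusted p = 3.81e-05) and the flap endonuclease FEN1 fell by 0.69 on the log2 scale, while MCM2 and MCM10 stood at 0.46 and 0.55 (camera adjusted p = 0.103). Of 24 mitosis genes 0 passed, over all genes or adjusted over the list alone, 0 had an unadjusted p under 0.05 and DESeq2 and limma-voom called 0, and TPX2, CENPE, KIF11 and CDK1 had values of 0.19, -0.27, 0.46 and 0.29 (camera adjusted p = 0.819). Of 16 p53 target genes, BBC3, a pro-apoptotic gene, rose (0.71, SE 0.21, adjusted p = 0.0492), while TNFRSF10B, CDKN1A and TIGAR had values of 0.47, 1.31 and 0.73, with 1.93 in #1 and -0.14 in #2 for CDKN1A (camera adjusted p = 0.0733). The WNT antagonist DKK1 fell from 290 to 147 ± 4.03 CPM (-0.98, SE 0.17), alone among 14 WNT target genes, whose median and test lay below 0 (-0.15, camera adjusted p = 0.269) and whose mean lay above (0.02); the median was 0.04 in #1 and -0.20 in #2, with CTNNB1, AXIN2 and ZNRF3 at -0.22, 1.62 and -0.28. Among 18 YAP and SRF target genes, the transcription factor SRF fell (-1.32, SE 0.25), as did CTGF (-0.95, SE 0.28), whereas ANKRD1 rose (0.69, SE 0.15; 0.91 in #1 and 0.43 in #2) and CYR61 stood at -1.05 (camera adjusted p = 0.0837). The same lists gave 2 falls in S phase, 1 rise in p53 targets, 1 fall in WNT targets, and 1 rise and 3 falls in YAP and SRF targets when adjusted over the list alone.

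Of 19 epithelial and mesenchymal genes, fibronectin FN1 (-0.56, SE 0.12) and keratin KRT8 (-1.07, SE 0.24) fell, with CDH1 and TWIST1 at -0.94 and 2.48, the latter from 6 counts in si-Control and with 2.84 in #1 and 0.25 in #2 (3 falls when adjusted over the list alone; camera adjusted p = 0.324). The median and test of this list lay below 0 (-0.02, with 0.02 in #1, -0.03 in #2 and 0.05 with library size alone) and its mean above (0.08). Of 21 glycolysis and hypoxia genes 1 fell, LDHA, the lactate dehydrogenase subunit (-0.70, SE 0.15; 2 falls when adjusted over the list alone; camera adjusted p = 0.0837), and ALDOA, ADM and GPI stood at -0.44, 1.03 and -0.37. The nucleolar chaperone NPM1 fell (-0.76, SE 0.13), alone among 22 ribosome biogenesis and MYC target genes (1 when adjusted over the list alone; camera adjusted p = 0.105), with RRS1, WDR43 and ODC1 at -1.18, 0.34 and -0.54. The lysosomal membrane protein LAMP2 fell (-0.90, SE 0.24), alone among 22 autophagy and lysosome genes (1 when adjusted over the list alone; camera adjusted p = 0.968), and CTSD, SQSTM1 and LAMP1 had values of -0.39, 0.33 and -0.29. Of 11 heat shock genes 0 passed (5 at an unadjusted p under 0.05, 1 rise and 1 fall when adjusted over the list alone, 0 by DESeq2 and 1 by limma-voom; camera adjusted p = 0.298), and HSPH1, HSPB1 and HSPA8 had values of 0.43, -0.35 and -0.34. Of 9 interferon-stimulated genes, 15 apoptosis regulators and 8 replication-dependent histone genes 0 passed in each, over all genes, adjusted over the list alone, by DESeq2 or by limma-voom, with 1, 0 and 0 at an unadjusted p under 0.05. Camera adjusted p was 0.202 for the interferon list, 0.968 for the apoptosis list and 0.876 for the histone list. The mean of the apoptosis list was -0.01, while its median and test lay above 0. The histone list had a median of 0.18, with -0.03 in #2. Among named list members that did not pass, leaving out a library also moved the values of COX5A, SRSF7, HSPB1, VMA21, ODC1, XBP1, CSTF2T, ZNRF3, CENPE, CDK1, U2AF1, SQSTM1, PAPOLG, SLC7A11, SIN3A, AKR1C2, KIF11 and AXIN2 by more than 1.5 times. DESeq2 did not call FEN1, BBC3, ANKRD1, CTGF, KRT8 or LAMP2, and CTGF was also not called with library size alone.

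Of 15 fibroblast and endothelial markers 6 could be tested and 0 passed, over all genes, adjusted over the list alone, at an unadjusted p under 0.05 or by DESeq2 or limma-voom. All 6 lay above 0 (median 0.77, camera adjusted p = 0.0605). The filter kept a row if a single library held enough counts. Markers near the floor could thus enter through a high value in a library labelled si-CPSF6. COL1A2, with 0.787 CPM in si-Control, 4.18 in #1 and 6.08 in #2, is such a case. The shared sign therefore cannot be read as a rise of these markers. COL1A1 had 4.72 CPM in si-Control and 12.4 ± 0.835 CPM in the libraries labelled si-CPSF6, and LUM 10.2 and 11.1 ± 1.5 CPM. KDR had 2 counts in si-Control, 9 in #1 and 19 in #2. Of 15 blood cell markers 4 could be measured, too few for the list test. LYZ had 129.7 CPM in si-Control and 129.8 ± 29.2 CPM in the libraries labelled si-CPSF6. CD14 and CD68 had log2 fold changes of -0.65 and 0.25, with -0.29 in #1 and 0.61 in #2 for CD68. ITGAM had a log2 fold change of 2.21 (SE 1.55), from 6 counts in si-Control, 16 in #1 and 12 in #2. No mitochondrially encoded gene was among the rows analysed here.

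Among abundant genes, the libraries labelled si-CPSF6 shared more change from the control than the simulation gave. At a mean of at least 50 CPM (4482 rows), 6 genes were at least 2-fold higher and 26 at least 2-fold lower in both libraries, where simulated unchanged libraries against the same control gave 0.35 and 0.120 on average, and independent lists of the same lengths would share 0.0535 and 0.471. The correlation across these genes of the log2 ratios was 0.699, against 0.475 in the simulation, and the covariance was 0.0904 against 0.0375. Over all 12923 tested rows the correlation was 0.433 against 0.455, the covariance 0.219 against 0.186, and 390 rows were 2-fold higher and 200 were 2-fold lower in both, against 257 and 205 in the simulation and 60.4 and 44.8 for independent lists, so over all rows the correlation and the count of lower genes were not above the simulation. Genes are not independent replicates, and with 1 control library the control could not be split, so a difference of the control library itself, which moves both ratios alike, could not be separated.

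Without a test, 1679 rows lay at least 2-fold apart between #1 and #2, where the simulation gave 1492 on average and at most 1605. Among rows with a mean of at least 10 CPM there were 446, against 429 on average and at most 481, and at 50 CPM 14, against 8.21 and at most 15, both within the range of the simulation, whose spread was estimated from the same libraries. Pearson's r across genes of log2 CPM was 0.927 between #1 and #2 and 0.938 between si-Control and each. The departure of counts from proportionality went the other way. Its chi-square per degree of freedom was 4.53 between #1 and #2, 9.60 between si-Control and #1, and 8.86 between si-Control and #2. Both measures depend on depth, which was greater in si-Control, so neither ranks the pairs by itself. Among genes with at least 50 CPM, the largest gaps with #1 above #2 were in MTFP1 (80.7 and 28.5 CPM), MRPS35 (118.7 and 53.2 CPM) and the kisspeptin receptor KISS1R (84.9 and 39.9 CPM). The largest gaps with #2 above #1 were in TAF1C (78.3 and 35.9 CPM) and the amino acid transporter SLC6A14 (60.4 and 28 CPM). These 5 genes were named after their values were seen; SLC6A14 also fell against si-Control (124 CPM, log2 fold change -1.48, SE 0.26). Of the cleavage factor Im subunits, NUDT21 stood at 57.3 CPM in si-Control, 73.2 CPM in #1 and 35.3 CPM in #2, and CPSF7 at 51.0, 55.6 and 49.8 CPM.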

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

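The thinned control, the removal of the most abundant genes and the count in each library alone were chosen after seeing the data. The count of 225 called genes (56 higher, 169 lower) was 222 with RLE size factors, 204 with library size alone, 222 with no filter, 191 at a mean of at least 10 CPM, 200 without the robust step, 205 with the control thinned to the depth of the others and 217 without the 50 most abundant genes. DESeq2 called 78 (15 higher, 63 lower; 74 shared), limma-voom 477 (123 higher, 354 lower; 222 shared), the likelihood ratio test 164 with 35 higher, and the test against a fold of 1.5 called 10 (1 higher, 9 lower). The last asks for a larger change; for the others the cause was not tested. Without either si-CPSF6 library no test was possible, and 1642 to 1648 genes lay at least 2-fold from the control.

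CPSF6 was not called with RLE size factors, library size alone, DESeq2 or limma-voom. The 10 called lists kept their call with both other scalings and with the thinned control. Each had adjusted p = 0.634 with an estimated correlation, a test that gave p = 0.0632 for a simulated list of independent genes moved 1.5-fold. That simulation does not bear on lists whose genes vary together. The estimated correlation was 0.857 for ribosomal protein genes, 0.582 for integrated stress response genes, 0.268 for ER chaperones and 0.217 for hepatocyte genes. It was 0.121 for complement genes, 0.116 for NRF2 targets, 0.0476 for NF-kB genes and 0.0421 for fatty acid genes. Cholesterol and oxidative phosphorylation genes had -0.0421 and -0.0267. Above the preset 0.01, the preset p may be too small. With 1 residual degree of freedom these estimates are rough. Leaving out each si-CPSF6 library, list medians ranged from -0.57 to -0.50 for hepatocyte genes, stayed at -0.21 for ER chaperones (-0.19 in the fit of both) and ranged from -0.16 to -0.14 for oxidative phosphorylation. They ranged more widely for NF-kB genes (-0.42 to -0.10), fatty acid genes (-0.53 to -0.18), complement genes (-0.64 to -0.26) and NRF2 targets (0.23 to 0.49). With the thinned control the p53 target list, median 0.28, was also called with the preset correlation; with all control counts it had adjusted p = 0.634 with an estimated correlation, which was not run on the thinned control.

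Of 133 named entries, 133 kept their side of the threshold with RLE size factors and 128 with library size alone. With DESeq2, 65 did, 15 lost their call and 2 gained one, and the others had no adjusted p. With limma-voom, 112 did, 1 lost its call and 20 gained one. No named gene changed direction while called. The correlation of the si-CPSF6 libraries' ratios, 0.433, was 0.540 at a mean of at least 10 CPM and 0.699 at 50 CPM; the cause was not tested. The count of genes 2-fold apart between #1 and #2, 1679, was 446 at 10 CPM, where fewer genes were compared and the simulation gave 429 on average and at most 481. No paired analysis was possible because the labels give si-Control no replicate number. At this depth the test called 0% of simulated 1.5-fold and 40.4% of simulated 2-fold changes.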

Other observations

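The tests of CPSF6 counts, swapped labels, other groupings of the libraries, depth, scaling, abundant genes and expression level were chosen only after the result was seen, as were the bounds for the share of lower genes and the interval of the GC test. The genes in this paragraph were likewise picked after their values were seen. Besides AREG, a second EGF receptor ligand, EREG, rose from 75.8 to 146 ± 11.8 CPM (SD, n = 2; log2 fold change 0.94, SE 0.22, edgeR adjusted p = 0.00264). The dioxin receptor AHR rose (0.73, SE 0.22, adjusted p = 0.0499) with its target CYP1A1, and 2 further targets, CYP1B1 and TIPARP, had values of 1.13 and 1.11 (adjusted p = 0.285 and 0.0779). The nonsense-mediated decay factors UPF2 and UPF3B rose by 0.57 and 0.83 on the log2 scale (UPF3B 1.08 in #1 and 0.53 in #2). Both subunits of the hepatocyte asialoglycoprotein receptor fell, ASGR1 from 199 to 97.0 ± 3.59 CPM and ASGR2 from 406 to 262 ± 4.74 CPM, as did the vitamin D carrier GC (-1.29, SE 0.14) and the protease inhibitor SERPINA5 (-1.19, SE 0.15). Translation factor EIF3C and its near-identical copy EIF3CL fell (-1.08 and -1.30), but how reads shared by the copies were counted is not known. The lncRNA KCNQ1OT1 fell by 0.55 on the log2 scale (-0.78 in #1 and -0.36 in #2).

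Of 5 genes of the early secretory pathway picked after their values were seen, 4 fell and 1 rose. KDELR1, which returns ER residents from the Golgi, fell from 1259 to 713 ± 63.3 CPM (-0.82, SE 0.12, adjusted p = 1.72e-08), and SURF4, SSR3 and TMED10 fell by 0.81, 0.51 and 0.52 on the log2 scale. SEC62, of the ER translocon, rose (0.43, SE 0.13, adjusted p = 0.0443).

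CPSF6 mRNA was not lower by 2-fold in either library labelled si-CPSF6. Counting error alone is argued against, since the exact binomial 95% interval of the ratio was 0.892 to 1.31 in #1 and 0.620 to 0.940 in #2. Both lie above a 2-fold decrease. Over both libraries the lower end of the fitted 95% interval of the fold was 0.625, which does not speak for #2 alone. The counting intervals leave out other variation between libraries, so a 2-fold fall in #2 cannot be excluded. The largest fold in CPSF6 CPM between any 2 of these 3 libraries was 1.41, so no exchange of their labels would give a measured 2-fold fall. A swap among them cannot be excluded, since an siRNA that lowered CPSF6 mRNA less than 2-fold would leave no such gap. Loss of CPSF6 protein without mRNA loss, recovery of the mRNA by day 2, a swap with a library outside the series and an ineffective siRNA may each remain possible, and none was tested.

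More called genes were lower than higher. With the control thinned to the depth of the others, 75.6% of called genes were lower (exact binomial 95% interval 69.1 to 81.3), and without the 50 most abundant genes 76.0% were (69.8 to 81.6), which argues against control depth and a few abundant genes as the cause. With library size alone the share was 59.3% (52.2 to 66.1) against 75.1% with TMM, so part of the imbalance goes with the scaling, and since genes are not independent and these intervals are too narrow, the rest cannot be told apart from it. Setting 1 library against the other 2 can be done in 3 ways, too few to judge chance: the real one gave 225 called genes, the highest of the others 7, and so 1 way gave as many. A difference of the single control library could give the same picture and was not testable.

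Hepatocyte genes were called lower as a list with the preset correlation, but not with an estimated one (adjusted p = 0.634). After a trend on GC content and transcript length was removed, their median moved from -0.60 to -0.50 (bootstrap 95% interval -0.64 to -0.33; 23 of 24 genes matched), which argues against that bias as the whole cause. High expression is argued against as well. The median lay at percentile 0 among 10000 lists matched on broad classes of expression, in the fit and in each library. It also lay at percentile 0 after the trend was removed, with matched genes drawn from the 100 rows nearest in expression. Matched genes were drawn independently, so these percentiles can overstate how unusual a list is whose genes vary together. What stays open is any other difference of the lone control culture, such as its density or transfection; an effect of the siRNA remains a hypothesis.

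Cleavage factor Im is known to favour distal poly(A) sites, so 3′ UTR length was set against the change in 8877 genes with at least 10 CPM. Spearman's rho across genes was 0.0768 over both libraries (0.0722 in #1 and 0.0617 in #2), against 0.0109 with the difference between #1 and #2. Of 4 equal groups by length, the shortest (median 195 nt) had a median log2 fold change of -0.06 and the longest (3473 nt) 0.03. The relation met the bound set for it beforehand but is very small, and a length bias of the single control library may give the same; the 2 cannot be told apart with 1 control.

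If the rise of AREG and EREG went with stronger EGF receptor signalling, ERK feedback genes might be higher. The median of 17 such genes, without AREG and EREG, was 0.37 (0.38 in #1, 0.33 in #2; 13 of 17 above 0), which met the bound set beforehand with the preset correlation (camera adjusted p = 0.00882) and not with an estimated one (adjusted p = 0.375). The list was made after the data were seen. It also held immediate-early genes such as FOS and EGR1 and a further EGF receptor ligand, HBEGF. Of the 17, 0 were called singly. DUSP5 had a value of 1.28, SPRY2 1.04 (SE 0.96, from 3.74 CPM in si-Control) and EGR1 -0.06 (0.06 in #1 and -0.19 in #2). Outside the list, the phosphatases DUSP9 and DUSP3 fell by 1.21 and 0.96. A higher ERK output is thus a hypothesis that 1 control library cannot settle.

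If the fall of secreted protein genes went with a smaller secretory apparatus, other genes of the early secretory pathway might be lower. The median of 31 such genes, without the 5 named above, was -0.15 (-0.20 in #1, -0.09 in #2; 21 of 31 below 0), which met the bound set beforehand with the preset correlation (camera adjusted p = 0.00957) and not with an estimated one (adjusted p = 0.375). With library size alone the median was -0.08. The list, made after the data were seen, also held genes of ER import and processing, namely SEC61, SSR, SPCS, RPN, DDOST, OSTC and STT3A genes. Of these, all but SEC61A1 (0.02) lay below 0. The ER to Golgi transport genes proper lay on both sides of 0, such as COPB1 at 0.34 and KDELR2 at -0.40, and showed no clear fall as a group. Of the 31, 0 were called singly, and the median lay at percentile 4.24 of lists matched on expression, so the shift is small and, with 1 control library, open.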
